A study of Mus musculus with 4 samples.

How the data were processed

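Single-cell RNA sequencing had been done on cells sorted into CD45-positive and CD45-negative fractions from MB49 tumours of male and female mice, 1 library for each of the 4 combinations. Per the labels' protocols, tumours were minced and digested with collagenases, DNase and dispase, red cells were lysed, live cells were sorted, and whole-transcriptome libraries with UMIs were made on the BD Rhapsody microwell system. The submitters' processing notes name CASAVA 1.8, UMI-tools and Seurat and the genome build mm10. How each tool was used, and the aligner, are not given in the sources used here. The deposited matrices hold UMI counts per gene and cell as whole numbers, not normalized, with genes given by symbol. A gene absent from a library's list was taken as a count of 0. Gene positions are from the GENCODE M21 annotation of mm10.

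From these counts, cells with at least 500 UMIs, at least 250 genes and at most 25% mitochondrially encoded UMIs were kept, 19372 of 22115 barcodes. Doublets were looked for in each library with Scrublet in scanpy 1.11.5 at an expected rate of 6%, but its own threshold marked 0, 2, 0 and 1 cells, too few for it to have worked on matrices that hold doublets. Whether doublets had been removed before deposit is not given in the sources used here. The marked cells were removed, and an alternative without the 5% of cells with the highest scores was added. The 4 libraries were clustered together on 2000 variable genes without the sex-linked genes, 30 principal components and 15 nearest neighbours, with the Leiden method (leidenalg 0.10.2, python-igraph 0.11.9, resolution 1.0), which gave 27 clusters. No integration between libraries was applied. Clusters were named from marker lists. These markers, the gene lists, the rule for named genes and the alternatives, except where stated, were fixed before the data were examined. The scoring of those markers was set after the data were seen: a cluster took the class whose markers lay, on average, closest to their highest cluster level, needed 3 detected markers, and stayed unnamed when 2 classes scored within 0.05. Macrophages, monocytes and type 2 dendritic cells were merged as mononuclear phagocytes. A total of 2 clusters with macrophage markers beside T cell or neutrophil markers were kept out of the classes as mixed, by a rule set after the data were seen: at least 5 macrophage markers, at least 3 core T cell or neutrophil markers and a median depth of at least 1.2 times that of the library.

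For each library and class, raw UMI counts were summed over cells and given as CPM of the sum, with exact Poisson intervals. Male:female ratios have exact conditional (binomial) intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). These intervals treat UMIs as independent, which they are not where 1 cell holds most of a gene's UMIs, so that share is given. A count of 0 in a ratio was set to 3 counts, which makes the ratio a bound, and the limit given for a level of 0 is also that of 3 counts. No p-value was computed. Classes were compared within a gate where each library had at least 100 kept cells, which gave 8 comparisons with the 2 whole gates. Eligible genes had at least 100 UMIs in the 2 libraries together and at least 100 CPM in the higher one, and were not sex-linked, mitochondrially encoded, ribosomal, haemoglobin, immunoglobulin or T cell receptor genes or unnamed gene models. The share of eligible genes within 2-fold was taken as the summary of a comparison after the ratios had been seen. The text names the 10 largest and 10 smallest male:female ratios of each whole gate, 8 and 8 of the 3 largest classes of a gate and 5 and 5 of other classes. For gene lists it names, from the members with the 2 largest and 2 smallest ratios and the 3 with most UMIs, a selection. Genes of near-identical families, such as the Gzmd to Gzmf, Mcpt, H2-Q and Ly6 genes, are uncertain where the counting could split reads between them. Members of a list needed 20 UMIs. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression (each member replaced by 1 of the 100 nearest genes on either side), as a description of these libraries. The 33 lists covered sex-linked, hormone, interferon, antigen presentation, lymphocyte, myeloid, tumour, stress and background genes. The report describes a part of them, chosen after their values were seen, and some single genes of these lists are not reported here.

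The ratio and list code was tested on simulated counts with 200 changed genes. For tumour cells, among 1913 genes, all genes changed 1.5-fold, 2-fold and 4-fold had the right direction (100% each), and 95.6% of unchanged genes had intervals that held the true value. For CD4 T cells, among 1833 genes, the direction was right for 100% of genes at each fold and 95.7% of unchanged genes had intervals that held the true value. These simulations hold Poisson noise only and say nothing of differences between animals.

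The alternatives were no cell filter, a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial), doublets kept, resolutions 0.5 and 2.0, each gate clustered alone, another seed, size factors by the median of ratios over genes with at least 50 UMIs, totals without mitochondrial, ribosomal and the 20 most abundant genes, the mean over cells of CPM, thinning to 1000 UMIs per cell, the same class in the other gate where both libraries held at least 50 cells, and list members with at least 100 UMIs. Added after the data were seen were the removal of the highest doublet scores and a minimum of 2000 UMIs per cell, clustered anew for shares and within the classes for expression. Figures were drawn with matplotlib 3.10.9.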

Results

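Tumours grown from MB49, a mouse bladder carcinoma line derived from a male mouse, were dissociated from male and female mice and sorted on CD45, the pan-leukocyte surface protein encoded by Ptprc. Single cells were captured in microwells on the BD Rhapsody system and their transcriptomes counted by unique molecular identifiers (UMIs). There were 4 libraries, 1 for each combination of host sex and gate. The deposited matrices held 5771 barcodes and 40644787 UMIs for the male CD45-positive library, 5169 barcodes and 37705608 UMIs for the female CD45-positive library, 6023 barcodes and 62273035 UMIs for the male CD45-negative library, and 5152 barcodes and 44601391 UMIs for the female CD45-negative library. Median UMIs per barcode were 5159, 5095, 9055 and 8007.5 in the same order. After the cell filter and doublet call 5379, 4593, 5496 and 3904 cells were kept. The filter removed the most barcodes from the female CD45-negative library, where 710 barcodes had too few UMIs, against 40 in the male one. With 1 library per group there was no replicate check of any difference between the sexes and no test across animals, so values are compared by size. The labels used here do not say how many mice or tumours each library pooled. All intervals are 95% intervals for counting error only, and the sex of the host cannot be separated from other differences between the libraries.

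The sex labels and the sort were checked first with genes that should follow them. Xist, the RNA that silences an X chromosome (chromosome X, 103460366 to 103483254 in mm10), had 0 UMIs in the male CD45-positive library, which at 3 counts allows up to 0.0744 CPM (UMIs scaled to a common library total), and 182 CPM (interval 177 to 186) in the female one. The Y-linked helicase gene Ddx3y (chromosome Y, 1260771 to 1286629) was at 151 CPM (148 to 155) in the male CD45-positive library and 0.375 CPM (0.205 to 0.628) in the female one. Ptprc was at 742 and 648 CPM in the male and female CD45-positive libraries and at 1.79 and 1.35 CPM in the CD45-negative libraries. In the CD45-negative gate the host and the tumour cells differed. Fibroblasts of the female host carried Xist at 212 CPM (177 to 252), whereas tumour cells of the same library carried it at 0.631 CPM (0.416 to 0.917). Tumour cells held Ddx3y at 10.1 CPM (9.37 to 10.98) in the male library and 16.3 CPM (15.1 to 17.6) in the female library, both far below the 121 CPM (83.3 to 170) of male fibroblasts.

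**Figure D1:**
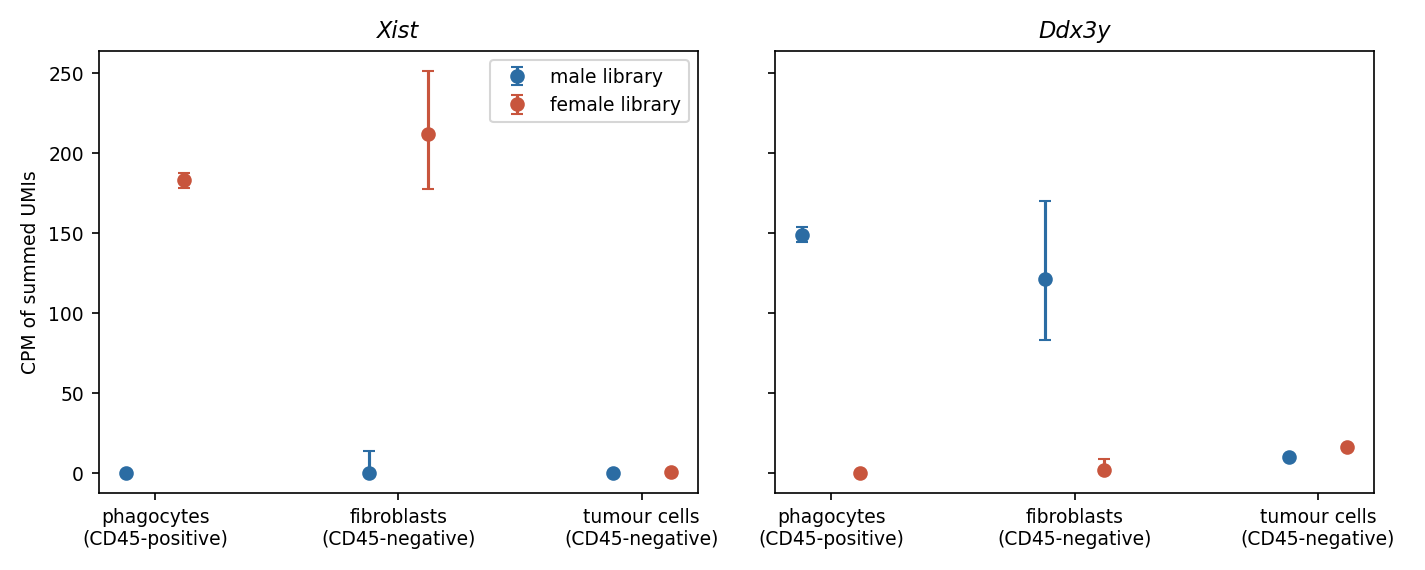
Summed Xist (left) and Ddx3y (right) in CPM for 3 cell populations of the male (blue) and female (red) libraries; bars are 95% Poisson intervals. Xist marks the female host cells and Ddx3y the male host cells, while tumour cells of the female library have Ddx3y at 16.3 CPM.

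The first comparison asked which immune cells the tumours of each sex held. Mononuclear phagocytes were the largest class in both CD45-positive libraries. Their clusters were named as macrophages, from markers such as C1qa and Apoe, or as type 2 dendritic cells, from markers such as Cd209a. No cluster scored highest for the monocyte markers, so monocytes were not told apart from macrophages. The class made up a larger share in the female library, 71.5% (70.2 to 72.8) against 50.5% (49.2 to 51.9), a female:male ratio of 1.41 (1.34 to 1.49). The classes with larger shares in the male library were neutrophils, with 12.6% (11.7 to 13.5) against 4.53% (3.95 to 5.17), CD8 T cells, with 7.72% (7.02 to 8.46) against 3.18% (2.69 to 3.73), and regulatory T cells, with 4.70% (4.15 to 5.30) against 1.59% (1.25 to 1.99). Type 1 dendritic cells (cDC1), which carry Xcr1 and Clec9a and cross-present antigen, had the largest ratio of these classes, 4.13% (3.61 to 4.69) against 0.414% (0.249 to 0.645), or 222 cells against 19. Their male:female ratio was 9.98 (6.24 to 16.9). Mature dendritic cells, marked by Ccr7 and Fscn1, were at 3.03% (2.59 to 3.52) and 2.11% (1.72 to 2.57).

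The shares of NK cells and CD4 T cells were not separated by their counting intervals. NK cells were at 4.76% (4.21 to 5.36) in the male and 4.83% (4.23 to 5.49) in the female library, and CD4 T cells at 3.81% (3.32 to 4.36) and 3.42% (2.91 to 3.99). The NK log2 male:female ratio of -0.02 was 0.29 at a finer clustering and 0.60 with at least 2000 UMIs per cell, where that of CD4 T cells was -0.40. Gamma-delta T cells, marked by Trdc and Cd163l1, were fewer in the male library, 9 cells against 29. Plasmacytoid dendritic cells numbered 19 and 22, and mast cells or basophils 16 and 5. A further 5.82% and 5.62% of cells fell in 2 clusters that combined macrophage markers with those of T cells or neutrophils, and they were kept out of the classes. Shares in a library add up to a whole, so a larger phagocyte share lowers every other share. Neutrophils had a median of 1243 UMIs in the male and 1188.5 in the female library, low enough that a minimum of 2000 UMIs per cell left no neutrophil class.

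**Figure D2:**
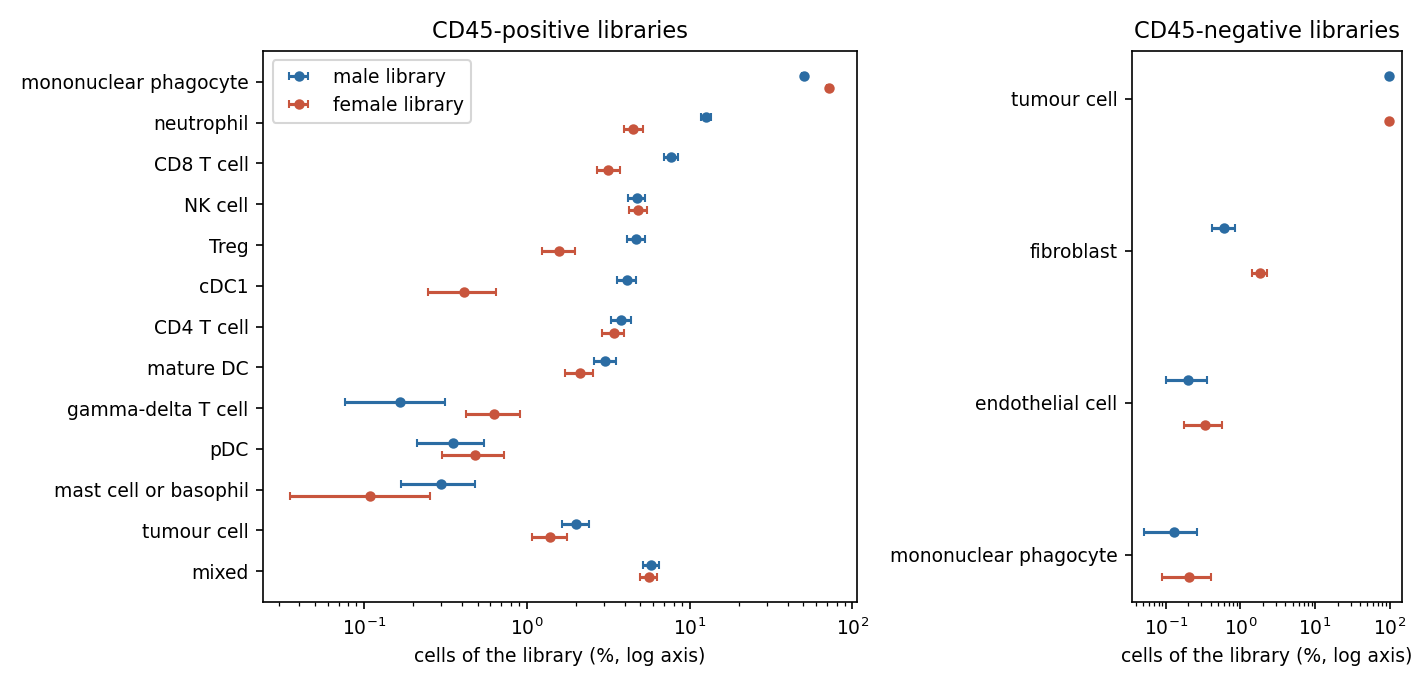
Share of each library's kept cells in each class (percent, log axis) for the CD45-positive (left) and CD45-negative (right) libraries; points are the male (blue) and female (red) library and bars are exact 95% intervals. The widest separation among the larger immune classes is that of cDC1, at 4.13% and 0.414%.

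In the CD45-negative gate nearly all cells were tumour cells in both sexes, 98.9% (98.6 to 99.2) in the male and 97.6% (97.1 to 98.1) in the female library. Fibroblasts made up 0.600% (0.414 to 0.842) of the male and 1.82% (1.42 to 2.29) of the female library, a female:male ratio of 3.03 (1.98 to 4.73), from 33 and 71 cells. Endothelial cells numbered 11 and 13, too few to separate their shares.

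The second comparison asked how gene expression differed between the sexes in the CD45-positive cells. Over the whole gate, 96.3% of the 1903 eligible genes had a male:female ratio within 2-fold. The largest ratio in the female library was that of Chil3, a chitinase-like protein of macrophages, which was 12.9-fold higher (12.2 to 13.5), and Arg1, which degrades arginine (chromosome 10, 24915221 to 24927484), was 6.12-fold higher (6.02 to 6.21), at 2880 against 471 CPM. Slc7a2, an arginine transporter, was 5.66-fold higher (5.50 to 5.84) and Fn1, fibronectin, 5.03-fold (4.92 to 5.14). Atp6v0d2, F7, Tmem26, Pecam1, Gpnmb and Nos2 followed, at 3.23-fold to 4.37-fold. The genes with the largest ratios in the male library included 4 mast cell protease genes: Mcpt2, with 5431 UMIs against 1 and 21.2% of the male UMIs in 1 cell, Cpa3, Tpsb2 and Mcpt4. Of the male UMIs of these 4 genes, 93.1% to 96.7% lay in the 16 mast cells or basophils. Cadm1, a marker of cDC1, was 5.47-fold higher in the male library (5.13 to 5.83), Cp 3.59-fold, Cx3cr1 3.53-fold, Ccl22 3.36-fold, Cxcl3 3.16-fold and S100a9 3.03-fold. Whole-gate ratios mix expression with the different shares of the classes, so the classes were compared next. Ratios and list medians within a class can still mix expression with the shares of its clusters. No male:female ratio was computed within a single cluster.

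Within mononuclear phagocytes (2719 male and 3285 female cells), Chil3, Arg1, Spp1 and the matrix protease list were higher in the female library, and the inflammatory myeloid and proliferation lists higher in the male library. Chil3 was 11.3-fold higher in the female library (10.7 to 11.9), Spp1, osteopontin, 5.43-fold (5.17 to 5.71), Arg1 5.43-fold (5.34 to 5.52), Fn1 5.16-fold (5.03 to 5.29) and Slc7a2 4.87-fold (4.72 to 5.03), followed by Atp6v0d2, Tmem26 and Ly6c2, a marker of classical monocytes, at 3.65-fold to 4.003-fold. In the male library Cadm1 was 5.61-fold higher (5.22 to 6.03), Cx3cr1, the fractalkine receptor, 4.26-fold (4.02 to 4.51), the neutrophil-attracting chemokine Cxcl1 3.42-fold (3.25 to 3.60) and Ccr7 3.26-fold (3.03 to 3.51), followed by Tmem176a, Tmem176b, the mitotic gene Ube2c and Nfkbiz at 2.77-fold to 3.07-fold. Different clusters held most of the class in the 2 libraries. Clusters led by Retnla, Ear2 and Mgl2 and by C6, Cx3cr1 and Fcrls held 866 and 733 male cells against 148 and 77 female cells, whereas clusters led by Chil3 and Arg1 and by Slc7a2, Mmp12 and Mmp13 held 1309 and 1074 female cells against 178 and 272 male cells. The type 2 dendritic cell cluster, led by Cd209a, Igkc and Jchain, held 343 male and 196 female cells. A cluster mostly of 1 library may be that library and not a cell state. The mitochondrially encoded list had a median log2 male:female ratio of 0.27 in these cells, above the random range of -0.28 to 0.21.

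Gene lists fixed in advance were then compared in phagocytes. Of the 30 lists with a median there, 15 lay below their random range, 8 above it and 7 inside. In tumour cells 12 of 28 lay below, 4 above and 12 inside. A median outside the range was therefore common and does not by itself single out a list. The proliferation list had a median log2 male:female ratio of 0.82, above the random range of -0.16 to 0.12, and 12 of its 15 measured members were at least 1.5-fold higher in the male library. Mki67 was 2.46-fold higher, at 172 against 69.9 CPM, and Top2a was at 242 against 110.5 CPM. NF-kB target genes had a median of 0.71, with 7 of 9 members at least 1.5-fold higher in the male library, among them Birc3 at 1.81-fold. Inflammatory myeloid genes also had a median of 0.71, with 8 of 13 members higher in the male library. Il1b was at 4094 against 2034 CPM and Cxcl1 and Il12b had the largest ratios, while Nos2, the inducible nitric oxide synthase, went the other way at 3.17-fold higher in the female library. Interferon-gamma response genes had a median of 0.36. Their largest ratios were those of Cxcl9, at 1586 against 609 CPM, and Cxcl10, both chemokines that attract activated T cells, whereas Socs1 was at 70.3 CPM in the female and 39.1 CPM in the male library.

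The lists with medians on the female side in phagocytes included tumour-associated macrophage genes (median -0.66; 8 of 14 members at least 1.5-fold higher in the female library, 3 in the male), matrix proteases (-1.14; 8 of 11 female, 1 male), hypoxia genes (-0.56; 6 of 12 female) and glycolysis genes (-0.47; 3 of 12 female). Mmp13 and Mmp12, a collagenase and an elastase, were 2.79-fold and 2.30-fold higher in the female library. Within the macrophage list the immunoregulatory cytokine Il10 went against the median, at 81.4 CPM in the male and 19.2 CPM in the female library, as did Apoe at 4282 and 2739 CPM. Adm and Ero1l, both hypoxia-induced, were 5.21-fold and 2.45-fold higher in the female library. Type I interferon-stimulated genes had a median of -0.31, with 2 of 15 members at least 1.5-fold higher in the female library. Complement genes did not separate, with a median of 0.01, inside the random range of -0.19 to 0.16. MHC class II genes had a median of 0.29 with no member beyond 1.5-fold. Lists of other cell types also lay on the female side inside the phagocyte class: cytotoxic effectors at -1.46 (8 of 10 members), collagens and matrix at -1.04 (9 of 12), neutrophil granule and receptor genes at -0.85 (5 of 9, and 1 on the male side) and the regulatory T cell list at -0.66 (6 of 9). The immunoglobulin list lay on the male side at 5.13 (4 of 4).

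**Figure D3:**
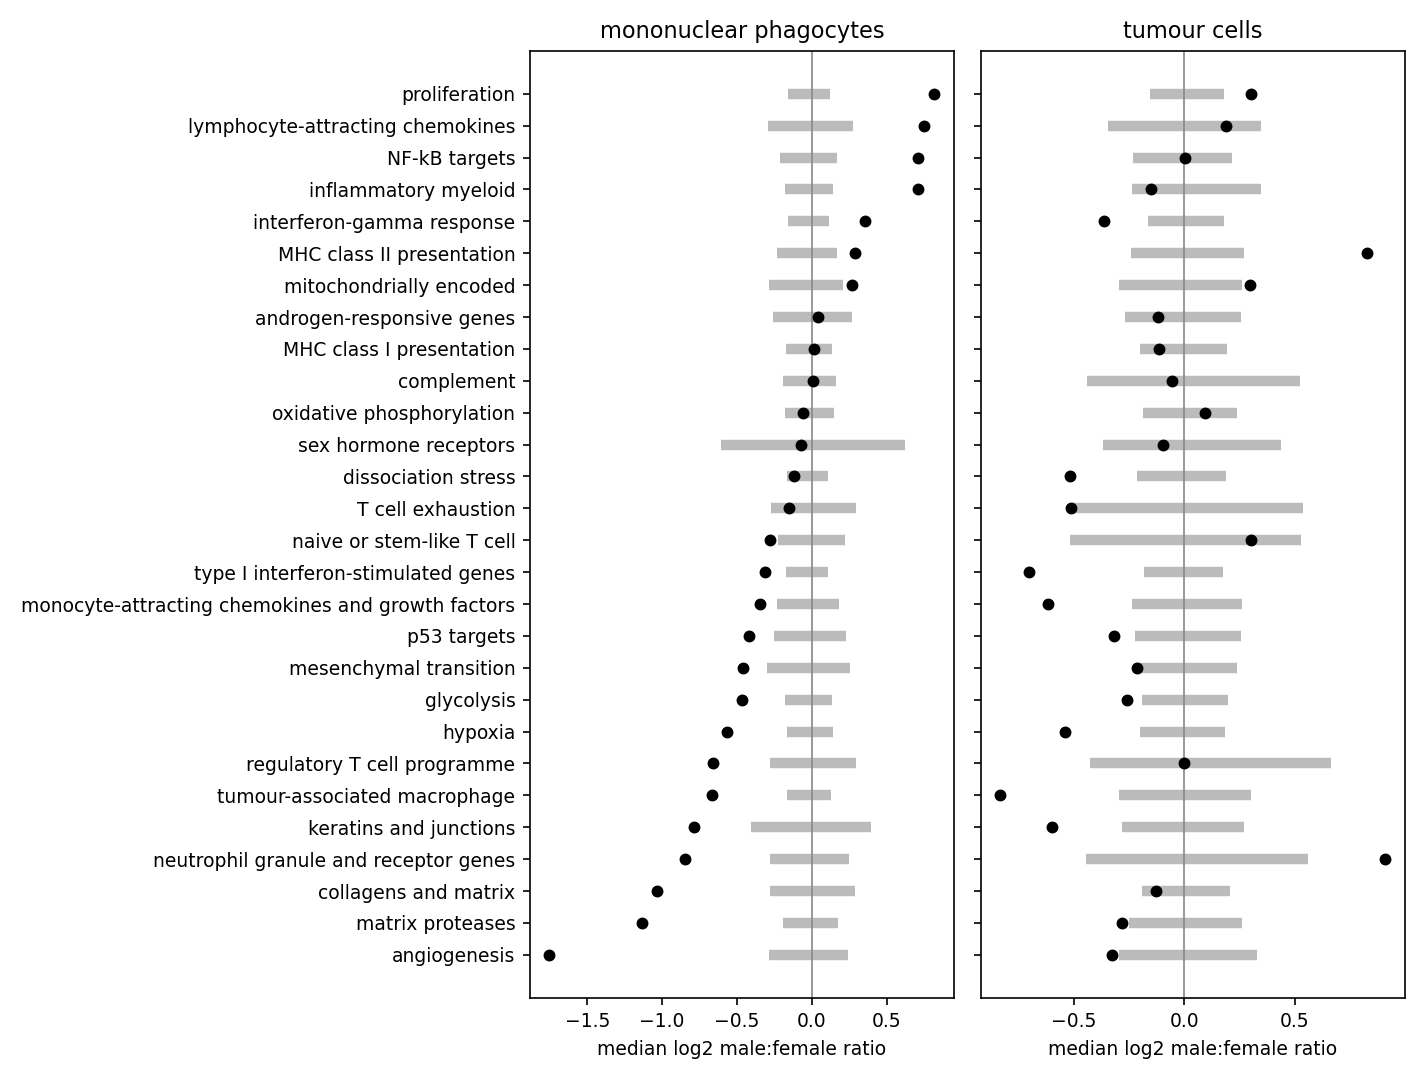
Median log2 male:female ratio of each gene list (black points) in mononuclear phagocytes (left) and tumour cells (right); grey bars span the middle 95% of medians of 10000 random expression-matched lists. In phagocytes proliferation lies at 0.82 and matrix proteases at -1.14, and in tumour cells MHC class II presentation lies at 0.83.

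CD8 T cells (415 male and 146 female cells) had higher levels of T cell exhaustion genes in the male library. The T cell exhaustion list had a median log2 ratio of 0.73, and 6 of its 10 measured members were at least 1.5-fold higher in the male library and none in the female. Pdcd1, which encodes the checkpoint receptor PD-1, was at 556 against 204 CPM, Rgs16 at 463 against 170 CPM, and Tox, a transcription factor of exhausted T cells, had 124 UMIs in 56 male cells against 1 UMI, a ratio of 39.8 (7.01 to 1584). Ctla4 did not differ by much, at 284 and 299 CPM. The regulatory T cell list was also on the male side in this class, with a median of 0.72 and 4 of 8 members at least 1.5-fold higher in the male library and 1 in the female. The male library is the one where regulatory T cells had the larger share. The naive or stem-like T cell list had a median of 0.50, with 4 of 8 members higher in the male library and none in the female, and of -0.13 with cells thinned to 1000 UMIs. Of the cytotoxic effectors, Gzma was 4.66-fold higher (4.25 to 5.11) and Gzmk 2.62-fold higher in the female library, whereas Prf1, perforin, was 2.98-fold higher in the male library. The granzyme genes Gzmd, Gzme and Gzmf had large ratios in the male library, but their UMIs came from 11, 9 and 13 male cells with about 30.1% to 35.5% of them in 1 cell. Serpinb9b shared this, with 31.1% in 1 cell. Nrgn, Pkp4 and Ubash3b were 10.4-fold, 5.46-fold and 5.17-fold higher in the male library. The other genes with large ratios in the female library (Ccl24, Arg1, Lmna, Mmp13, Ccl6, Mmp12 and Mrc1) were mostly phagocyte genes, and the C1q genes, which phagocytes make, were also higher there, at 1421 against 691 CPM summed over C1qa, C1qb and C1qc.

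NK cells (256 male and 222 female cells) had higher cell cycle genes in the male library and higher effector genes in the female library. The NK cluster also showed 4 core T cell markers, so the class may hold T cells. Their part in these differences was not tested. The proliferation list had a median log2 ratio of 0.83, with 13 of 15 members at least 1.5-fold higher in the male library, and Gmnn, Ccna2, Spc24, Pclaf and Hmgb2 had the largest ratios of single genes, 2.46-fold to 3.16-fold. The cytotoxic effector list had a median of -0.63, with 5 of 10 members higher in the female library. Gzma was at 6531 against 3200 CPM and Ifng at 129 against 29.2 CPM, while Prf1 differed little, at 574 CPM in the female and 603 CPM in the male library. Ifitm1 was 11.2-fold higher (8.65 to 14.7) in the female library, with its female UMIs in 68 cells and 24.04% of them in 1, and Ly6a 6.64-fold (5.09 to 8.77). Fn1, Mmp13 and Arg1 were also higher there, together with summed C1q genes at 1294 against 533 CPM.

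CD4 T cells (205 male and 157 female cells) gave several named genes that rested on single cells and others that phagocytes make. Sod3, Col1a1, Sparc and Ccl2 had ratios of 8.48-fold to 52.0-fold in the male library, but 1 cell held between 93.1% and 98.7% of the male UMIs of each, and with the stricter cell filter Sod3, Sparc and Ccl2 turned to the female side. Xcl1 had 96 UMIs in the female library with 96.9% of them in 1 cell. Idi2 was 13.9-fold higher (7.08 to 31.1) in the male library, from 11 male cells with 27.4% of the UMIs in 1 of them. Arg1, Mmp13, Mmp12 and Ccl24 were 6.30-fold to 8.66-fold higher in the female library beside summed C1q genes at 1544 against 886 CPM. The regulatory T cell list had a median of 0.03, although Il2ra was 2.06-fold higher in the female library.

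Neutrophils (677 male and 208 female cells) had higher levels of the chemokine genes Cxcl3 and Cxcl2 in the male library. Cxcl3 was 3.15-fold higher (2.84 to 3.51), at 4288 against 1359 CPM, and Cxcl2, the class's most abundant inflammatory gene, was at 38541 against 24631 CPM. The inflammatory myeloid list had a median log2 ratio of 0.28, with 3 of 10 members at least 1.5-fold higher in the male library, and of -0.0073 with classes from a coarser clustering. The monocyte-attracting list had a median of -0.87, with 5 of 9 members at least 1.5-fold higher in the female library. It also lay on the female side in phagocytes (-0.35), CD8 T cells (-1.32), NK cells (-1.79) and CD4 T cells (-0.82). What part phagocyte RNA had in the neutrophil value of this list was not tested. The lymphocyte-attracting list had a median of -0.71, with 2 of 4 members at least 1.5-fold higher in the female library. Its median turned to 0.15 without a cell filter and 0.43 at the coarser clustering. Fbxl5, Gabpb1, Tmcc1, Lamb3, H2-Q10, St3gal6 and Psd4 had male ratios of 2.27-fold to 2.82-fold. The granule genes Ngp, Ltf and Mmp8 were higher in the female library, but in few cells. Ngp had 334 UMIs in 2 female cells, 1 of them with 56.9%. For Ltf and Mmp8 1 cell held 57.1% and 46.0% of the female UMIs. The list of neutrophil granule and receptor genes had a median of -0.58, below the random range of -0.26 to 0.20, with 5 of 10 members at least 1.5-fold higher in the female library and none in the male, and of -0.018 as a mean over cells. S100a8 was at 7312 CPM in the male and 7423 CPM in the female library, and S100a9 at 7674 and 6977 CPM. Ccl24, Mmp12, Mmp13, Fn1 and Arg1 were also higher in the female library, with summed C1q genes at 1494 against 795 CPM. For Ccl24 and Fn1, 1 cell held 51.2% and 43.1% of the female UMIs.

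**Figure D4:**
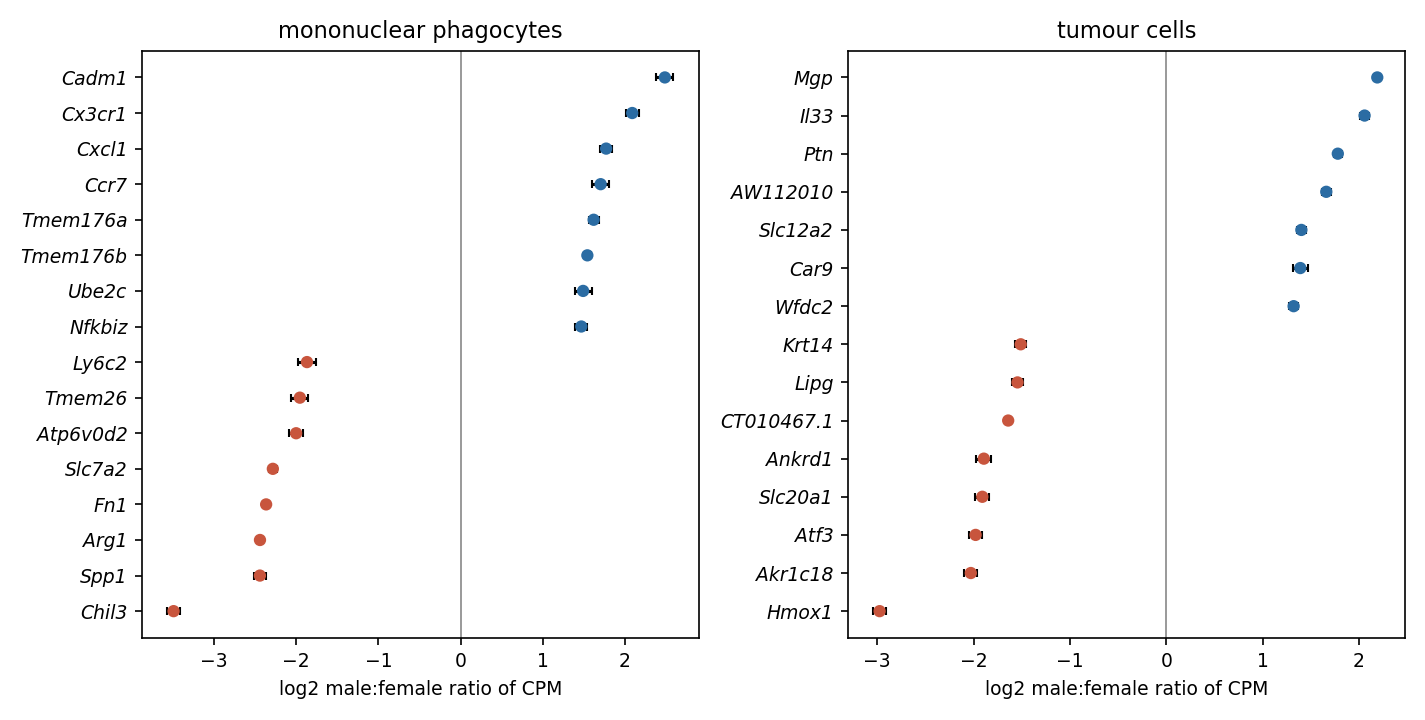
Log2 male:female ratio of CPM for the genes named by the fixed rule in mononuclear phagocytes (left) and tumour cells (right), with 95% counting intervals; blue marks genes higher in the male and red genes higher in the female library. Fgb is not drawn because it had 0 UMIs in the female library. Chil3 and Hmox1 lie farthest to the female side.

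The third comparison asked how expression differed in the CD45-negative cells. Tumour cells were 5436 of the male and 3811 of the female cells, and the class is described in place of the gate. Map1lc3a and Plet1, named for the whole gate, were 2.36-fold and 2.33-fold higher in the male library there and 2.36-fold and 2.31-fold in the tumour cells. Tnfaip6 and Col1a2 were 2.63-fold and 3.52-fold higher in the female library over the gate and 1.64-fold and 2.98-fold in the tumour cells. Among the tumour cells, 97.53% of the 2061 eligible genes had a ratio within 2-fold. Fgb, the fibrinogen beta chain (chromosome 3, 83040141 to 83049863), had 14939 UMIs in the male library and 0 in the female library, at least 3491-fold higher with the female count set to 3. Mgp, an inhibitor of calcification, was 4.56-fold higher (4.49 to 4.63) in the male library, the alarmin Il33 4.16-fold (4.03 to 4.30), the heparin-binding growth factor Ptn 3.43-fold (3.34 to 3.53) and AW112010 3.16-fold (3.06 to 3.26), followed by Slc12a2, Car9 and Wfdc2. In the female library Hmox1, the haem-degrading oxygenase (chromosome 8, 75093621 to 75100589), was 7.87-fold higher (7.53 to 8.23), Akr1c18 4.08-fold (3.90 to 4.27), the stress-induced factor Atf3 3.94-fold (3.77 to 4.13), Slc20a1 3.76-fold, Ankrd1 3.72-fold, Lipg 2.92-fold and Krt14, a basal keratin, 2.85-fold. CT010467.1 was 3.12-fold higher, at 2333 against 748 CPM, but its sequence resembles ribosomal RNA and its counts are uncertain. Different clusters held most of the tumour cells in the 2 libraries: 3 clusters, led by Anln and Mybl1, by Orm1 and Map1lc3a, and by Fgb and Itih2, held 1916, 1658 and 391 male cells against 322, 227 and 7 female cells, and clusters led by Akr1c18 and Anxa8 and by Anln and Sprr1b held 1515 and 1104 female cells against 537 and 218 male cells.

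Tumour cells of the male library had higher MHC class II genes. The list had a median log2 ratio of 0.83, with 7 of 8 members at least 1.5-fold higher in the male library. H2-Aa was at 366 against 170 CPM, H2-Ab1 at 299.6 against 138 CPM and Cd74 at 439 against 278 CPM. The phagocyte gene C1qa was at 0.344 and 0.467 CPM in the same cells, whereas the immunoglobulin gene Igkc, a marker of plasma cells, was at 120 and 11.3 CPM. Among the male tumour clusters Igkc and H2-Aa were at 22.8 and 146 CPM in the one led by Akr1c18, at 222 and 533 CPM in the one led by Orm1 and at 339 and 608 CPM in the one led by Fgb. In the 108 and 64 tumour cells found in the CD45-positive libraries the median turned to -0.64, with Ptprc at 23.4 and 65.7 CPM in those cells. MHC class I genes had a median of -0.12, inside the random range of -0.20 to 0.19. The proliferation list had a median of 0.30 with no member beyond 1.5-fold.

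Interferon, hypoxia and stress lists had medians on the female side in tumour cells. Type I interferon-stimulated genes had a median log2 ratio of -0.70, and 8 of 15 members were at least 1.5-fold higher in the female library, among them Isg15 at 2.16-fold and Ifit1 at 2.12-fold. A tumour cluster led by Ifit3, Ifit1 and Cmpk2 held 171 of the 5436 male and 259 of the 3811 female tumour cells. Interferon-gamma response genes had a median of -0.36, with 3 of 15 members higher in the female library, led by Cd274, which encodes PD-L1, at 36.3 against 15.3 CPM. The hypoxia list had a median of -0.54, with 6 of 12 members higher in the female library. Ero1l was at 1716 against 803 CPM and Adm at 197 against 82.2 CPM, whereas Car9, itself hypoxia-induced, was 2.62-fold higher in the male library. Dissociation stress genes, which rise during tissue digestion, had a median of -0.52, with Atf3 the largest ratio and Fos at 2043 against 1410 CPM, and the mitochondrially encoded list had one of 0.30, on the male side. The p53 target list had a median of -0.32, with Mdm2 at 551 against 228 CPM and Cdkn1a at 549.5 against 298 CPM, and one of 0.027 in the tumour cells of the CD45-positive libraries.

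The lists of the sex hormone response had medians inside their random ranges in tumour cells. The sex hormone receptor list had a median of -0.10, inside the random range of -0.37 to 0.44, with Esr1 2.34-fold higher in the male library at 7.74 against 3.32 CPM. The androgen-responsive list had a median of -0.12, inside the range of -0.27 to 0.25. Of its 9 measured members, 1 was at least 1.5-fold higher in the male library and 0 in the female. The mean log2 ratio was 0.39, so the median does not reflect that member.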

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

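The male:female direction of 2 gene lists differed between the gates while both medians lay outside the random range. The difference itself was not tested, since there is 1 library per group. The tests on carry-over from the male libraries and on host epithelium were chosen after the results they use had been seen. The test of thinned counts, the 2 of phagocyte RNA, that of co-occurring Y-linked genes and that of Fgb in other clusters were written before their values were seen, for patterns already noticed.

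The interferon-gamma response list had a median log2 male:female ratio of 0.36 over the CD45-positive cells and -0.36 over the CD45-negative cells. The CD45-positive classes did not all share this direction. The median was 0.36 in phagocytes and 0.07 in NK cells, but -0.46 in CD8 T cells, below the random range of -0.32 to 0.25. CD4 T cells and neutrophils lay at -0.25 and -0.31, inside their ranges. The T cell exhaustion list had medians of 0.50 over the CD45-positive and -0.69 over the CD45-negative cells. It was 0.73 in CD8 T cells, but -0.57 in NK cells and -0.28 in CD4 T cells, both below their random ranges. Phagocytes and neutrophils lay at -0.15 and -0.45, inside their ranges. In the CD45-negative cells the exhaustion list rests on genes that are not specific to T cells. Havcr2, for instance, was at 65.9 CPM in the female and 15.8 CPM in the male library.

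Phagocyte genes such as Arg1, Mmp12 and Mmp13 were higher in the female library inside every lymphocyte class compared and in neutrophils. Scaled by the C1q genes, which gave 14.5% to 17.3% of the phagocyte level in female lymphocytes and 5.37% to 8.93% in male ones, phagocyte RNA predicted the female levels of the macrophage-associated list in lymphocytes with a median observed over expected of 0.935 (interval 0.830 to 1.04, 32 values), and in neutrophils of 1.39 (1.21 to 1.66, 11 values), although for male neutrophils, which the test left out, it was 2.23. For male CD8 T, NK and CD4 T cells, also left out, it was 1.35, 1.28 and 0.993. The 32 values largely repeat the same genes in CD8 T, NK and CD4 T cells, so they are not independent. Both intervals cover the counting error of the observed UMIs only, not that of the expected levels. Thinning to 1000 UMIs left the lymphocyte list median at -1.94. Thinning keeps each gene's expected share within a cell, so this value cannot decide whether depth plays a part. From the C1q scaling, RNA of phagocytes counted with these cells, as free RNA, attached fragments or doublets, is a candidate source. Which of these it is stays open. Members the cells may make themselves went above the C1q-scaled level, such as Spp1, Vegfa and Cd9 in neutrophils and NK cells.

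Tumour cells of the female library held Y-linked RNA: 287 of 3811 cells (7.53%, 6.71 to 8.41) had a Ddx3y UMI. In the male library 252 of 5436 tumour cells (4.64%, 4.09 to 5.23) had one. Carry-over from the male CD45-negative library at the rate of Ddx3y would have brought 16842.5 Fgb UMIs, and 0 were found; carry-over from the male CD45-positive library would have brought 3428 Ptprc UMIs, and 59 were found. Both values go against carry-over in proportion to Ddx3y, but they had been seen when these tests were chosen. Ddx3y itself had 699 UMIs in tumour cells of the female CD45-negative library and 620 in those of the male one. The lower male count also goes against the male CD45-negative library as the source. The other Y-linked genes lay in the female library's Ddx3y cells 9.23 times (8.70 to 9.71) as often as those cells' share of UMIs predicts. In the male library's tumour cells the value was 12.6 (11.6 to 13.5), so the pattern is in both libraries. A minority of MB49 cells that kept the Y chromosome of the line may account for this, as a hypothesis from the same data.

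The cluster with Fgb held 391 male and 7 female cells of the CD45-negative gate. Its Ddx3y level was 0.0350 times that of male host fibroblasts, which argues against epithelium of the host. The other tumour clusters of that library held Fgb at 17.8 CPM against 3685 CPM in this cluster, 0.00482 times its level. The cluster, also led by Itih2 and Fetub, was picked for this test by its high Fgb. The value is therefore not used to exclude free RNA or doublets, which stay open. A subpopulation of tumour cells that grew in the tumour or tumours of that library, or an effect of host sex, may also remain, and 1 library per sex gives no test between them.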

How the results depend on the processing

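No paired analysis was possible because each group has 1 library. The removal of high doublet scores and the minimum of 2000 UMIs were chosen after seeing the data; the other alternatives were fixed before. Of 87 share ratios under alternatives 77 stayed inside the main counting interval, 10 moved and 0 called ones turned, while those of CD4 T and NK cells, whose intervals include 0, took either sign; 75 of 82 shares of genes within 2-fold, 1035 of 1258 named-gene ratios and 2180 of 2540 list medians also stayed inside. The cDC1 log2 share ratio ranged from 3.32 to 3.79 and the neutrophil one from 1.46 to 1.56. No neutrophil class was left at 2000 UMIs, and CD8 and CD4 T cells had no class at resolution 0.5. Only tumour cells could be compared in the other gate. Keeping doublets restores 3 cells and moved no result beyond its interval. The cause of the shifts below was not tested, unless named.

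Log2 share ratios that moved: with at least 2000 UMIs, clustered anew, phagocytes -0.27, CD4 T cells -0.40, regulatory T cells 2.06 and NK cells 0.60; without a cell filter CD8 T cells 1.66 and NK cells 0.32; with the stricter filter 1.60 and 0.30; NK cells 0.29 at resolution 2.0 and 0.29 with gates clustered alone. Percentages of eligible genes within 2-fold moved in neutrophils to 97.8 without a filter, 93.9 thinned and 97.4 at resolution 0.5, in CD8 T cells to 94.7 as a mean over cells and 93.2 thinned, and thinned in NK cells to 93.3 and CD4 T cells to 93.5. Thinning leaves fewer UMIs per gene.

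Of list medians, 138 of 2540 took the other sign. Those that lay outside their random range and turned were: in CD45-positive cells MHC class II to -0.074 (mean over cells) and -0.043 (thinned), in CD45-negative cells the regulatory T cell list to -0.0078 (thinned). Phagocytes: naive T cell list 0.11 (mean over cells) and 0.18 (at least 100 UMIs). Neutrophils: MHC class II 0.35 and lymphocyte chemokines 0.15 (no filter), 0.44 and 0.43 (resolution 0.5), inflammatory myeloid -0.0073 (resolution 0.5), collagens -0.59 (high doublet scores removed). CD8 T cells: cytotoxic 0.062 (mean over cells), inflammatory myeloid -0.37 (mean over cells), -0.51 (thinned), -0.049 (high doublet scores removed) and -0.45 (at least 100 UMIs), naive -0.13, collagens -1.23 and keratins -0.70 (thinned), collagens -0.59 (high doublet scores removed). CD4 T cells: inflammatory myeloid 0.98 (stricter filter), 0.027 (mean over cells), 0.10 (thinned) and 0.41 (high doublet scores removed), collagens -1.01 (stricter filter), exhaustion 0.0017 (thinned). Tumour cells of the CD45-positive libraries: MHC class II -0.64, neutrophil granule list -0.36 and p53 targets 0.027. Named genes that turned in CD4 T cells: with the stricter filter Sod3 -0.17, Sparc -2.07, Ccl2 -0.14 and Xcl1 2.57, and Xcl1 2.35 without high doublet scores.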

Other observations

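Igkc, the immunoglobulin kappa constant gene, was chosen after its values were seen. It was at 120 CPM (117 to 123) in tumour cells of the male library and 11.3 CPM (10.3 to 12.4) in those of the female library, and no B cell or plasma cell class was found. Among the male tumour clusters it ranged from 22.8 CPM in the cluster led by Akr1c18 to 339 CPM in the cluster led by Fgb. In mononuclear phagocytes all 4 measured immunoglobulin list members were at least 1.5-fold higher in the male library, with a median log2 ratio of 5.13. Igkc was at 236 against 1.89 CPM there and Ighm at 148 against 15.1 CPM, and Igkc and Jchain were among the leading genes of the type 2 dendritic cell cluster.

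Chemokines and growth factors that attract monocytes went both ways in tumour cells. The list had a median log2 male:female ratio of -0.62, with 6 of 11 members at least 1.5-fold higher in the female library and 1 in the male. Ccl8 was at 20.6 CPM in the female and 3.11 CPM in the male library, while Ccl2, the most abundant member, was at 849 and 1160 CPM and Csf3 at 6.66 and 29.0 CPM. Of the matrix genes, Col1a1 was at 3427 CPM in the male and 2752 CPM in the female tumour cells and Tnc was 1.92-fold higher in the male library, while the list had a median of -0.13, inside the random range.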
